A study of Mus musculus and Homo sapiens with 8 samples.

How the data were processed

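RNA was taken from MHC-II-high and MHC-II-low cells of bone marrow cultures with GM-CSF and IL-4, with 4 biological replicates per group. The labels state 5 days of culture in one place and 6 days before sorting in another. Per the labels, RNA was extracted with a column kit, converted to Cy5-labelled cRNA with Agilent's Quick Amp kit, and 750 ng was hybridized with Cy3-labelled Universal mouse reference RNA. The organism label of the reference channel names human, while its source name and sample type describe a mouse pool; it was taken as mouse. Replicate numbers came from the labels. The labels call the replicates biological without saying whether they were separate mice or cultures, so p-values measure only the spread between these samples.

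Per the file headers, the arrays (design 014868) were read with Feature Extraction 10.7.3.1. Per the file headers, the deposited scanner files hold spot and background intensity in both channels on a linear scale. They also hold intensity values that Feature Extraction had background-subtracted and dye-normalized. Per the file headers, their log ratio column is log10 of red over green; it was read only to check the direction of the ratio. Other columns of the deposited files are flags set by the scanner software, and of these the flags for signal well above background, for outlying spots and for saturation were used. The authors also deposited a table of log2 values with 1 value for each of the 41174 probes and each array. Each column of it, set against the log2 ratio of the same array computed as below, had a correlation of 1 and a slope between 1 and 1.001, so its scale is log2 and its direction is sample over reference; column medians were 0.00992 to 0.0149. The submitters' processing notes name limma, and its version is not given in the sources used here.

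Median spot signals were corrected for median local background by normexp with an offset of 50 in limma 3.58.1 (R 4.3.3). Mean spot signals had been planned, and the files hold medians. Loess normalization was run within each array with control spots at weight 0. Control spots and spots marked as outliers (118 to 166 per array) were then left out, and spots of one probe were averaged. Probes were kept where the sample channel was well above background on at least 4 of the 8 arrays, which left 22493 probes. For each accession the probe with the highest mean brightness over all arrays was used, giving 17755 transcripts, 17753 of them with a value on every array. The groups were compared with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over the transcripts tested; a transcript changed where the adjusted p was under 0.05. No covariate was used.

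The fit was tested on simulated data for the comparison of MHC-II-high with MHC-II-low over 17755 transcripts. It recovered 34% of transcripts changed by 0.25 log2, 82% of those changed by 0.5, and 100% of those changed by 1 or by 2 (50 of each), with 4 false calls beside 158 true ones. The simulation changed few transcripts and drew their errors independently, while 67.2% changed in the data. The limit that adjustment sets on single p-values differs with that share. These rates and false calls therefore describe the simulated setting, and not the sensitivity of the comparison itself.

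Lower bounds for transcripts not well above background in one group were computed from the sample channel after loess and Aquantile normalization, as the mean of the brighter group against the mean, over the dimmer group, of the higher of the transcript's own value and the lowest value well above background. The spike-in value of an array is the mean over 10 E1A probes (32 spots each, median per probe) of the log2 ratio before loess, minus the median over kept probes. Single values were compared by exact permutation tests.

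The files do not pair accessions with gene names, and no annotation was used. For this reason the 33 gene lists, the cell type markers among them, and the genes fixed by symbol before the data were examined were not tested. The rule for named genes took transcripts past an adjusted p of 0.05 whose groups do not overlap and whose sample channel is well above background on all 4 arrays of the higher group, by the largest rise and fall; its condition of a gene symbol could not be applied, and the first 2 in each direction are named. Alternatives covered the background correction, the normalization within and between arrays, the sample channel alone, the deposited log2 table, the filter on dim probes, the rule for several probes, the eBayes options, array weights, a test against a log2 difference of 1, blocks for slide and replicate number, and each array left out in turn. The spike-in scale and the within-slide fits, with the direction read from one slide to the other, were added after the data were seen.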

Results

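Gene expression was measured on 8 two-colour Agilent mouse arrays in cells that the labels name as dendritic cells grown from bone marrow. The cells came from wild-type C57BL/6 mice and were grown from marrow progenitors with GM-CSF and IL-4, a pair of cytokines that drives marrow cells towards dendritic cells. Flow cytometry then separated cells with much MHC class II on their surface (MHC-II-high), which the labels call spontaneously activated, from cells with little of it (MHC-II-low), which the labels call inactive. MHC class II is the surface molecule with which dendritic cells present peptides to helper T cells. Each group had 4 biological replicates, with 1 array per replicate. Sample RNA was labelled with Cy5 and the same pooled mouse reference RNA was labelled with Cy3 on every array, so each spot gave the log2 ratio of a sample to that reference.

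Between 21114 and 25905 of the 41174 probes were well above background in the sample channel of an array. The mean was 23190 ± 1840 probes (SD, n = 4) in MHC-II-high and 22114 ± 799 (SD, n = 4) in MHC-II-low, a difference that did not pass an exact permutation test (two-sided, p = 0.429, adjusted p = 0.628 over 11 measures per array). No spot was saturated. After the filter on dim probes, 17755 transcripts, each standing for 1 accession of the array design, were compared. The array files pair probes with accessions and not with gene symbols, so transcripts are given by accession, and at most 2 in each direction are named. Across transcripts, the log2 ratios of 2 arrays of one group correlated at 0.985 to 0.994 within MHC-II-high and at 0.988 to 0.995 within MHC-II-low. Arrays of different groups correlated at 0.866 to 0.884. The first principal component held 89.0% of the variance between arrays and separated the groups, and the second held 3.50%. The number of arrays limits the precision.

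The design asked which transcripts differ between MHC-II-high and MHC-II-low cells. The 2 largest rises in MHC-II-high were those of NM_011454 and NM_025359. NM_011454 stood at 4.00 ± 0.22 (SD, n = 4) log2 over the reference in MHC-II-high and at -0.20 ± 0.26 (SD, n = 4) in MHC-II-low, so that it was 18.4-fold higher in MHC-II-high (log2 difference 4.198, SE 0.13, limma adjusted p = 3.18e-10). NM_025359 stood above the reference in MHC-II-high (1.74 ± 0.14, SD, n = 4) and below it in MHC-II-low (-2.39 ± 0.21, SD, n = 4). It was 17.5-fold higher in MHC-II-high (log2 difference 4.13, SE 0.10, adjusted p = 8.38e-11). On this scale the 2 largest falls were smaller. NM_026439 went from 1.50 ± 0.24 (SD, n = 4) in MHC-II-low to -1.44 ± 0.11 (SD, n = 4) in MHC-II-high (log2 difference -2.94, SE 0.11, adjusted p = 1e-09). NM_013652 was far above the reference in MHC-II-low (3.71 ± 0.21, SD, n = 4) and less so in MHC-II-high (1.31 ± 0.26, SD, n = 4), a log2 difference of -2.40 with an SE of 0.13 (adjusted p = 1.81e-08). For each of these 4 transcripts the 4 arrays of one group lay entirely apart from the 4 of the other, and the sample channel was well above background on all 8 arrays. The order of sizes depended on the scale: on a scale set by spike-in controls, described below, the log2 difference was 3.91 for NM_011454, 3.83 for NM_025359, -3.95 for NM_026439 and -3.34 for NM_013652.

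**Figure D1:**
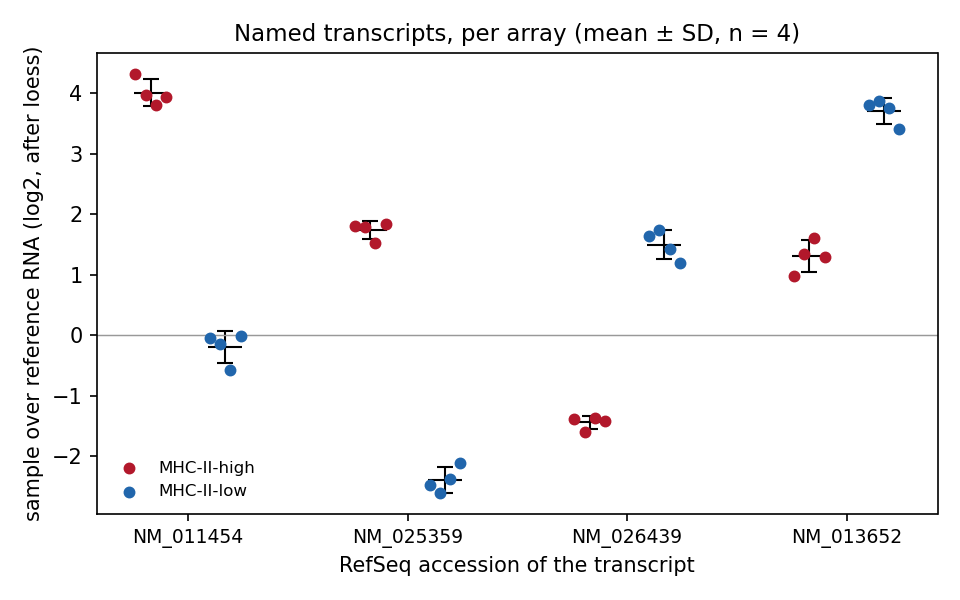
Log2 ratio of sample to reference RNA (y axis, after loess) for the 2 transcripts with the largest rise and the 2 with the largest fall in MHC-II-high (x axis, by accession); each point is 1 array, and bars give the mean ± SD of 4 arrays. The groups do not overlap for any of the 4 transcripts: NM_011454 averages 4.00 in MHC-II-high against -0.20 in MHC-II-low, and NM_026439 averages -1.44 against 1.50.

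These transcripts were the ends of a wide difference between the 2 populations. At an adjusted p under 0.05, 11924 of the 17755 transcripts changed (67.2%), of which 6224 were higher and 5700 lower in MHC-II-high. Most changes were small, with a median size of 0.47 log2 among changed transcripts against a median SE of 0.07 over all tested. A change of at least 2-fold was found for 1620 transcripts (9.12% of those tested), of which 1024 were higher and 596 lower in MHC-II-high. At 4-fold or more, 182 transcripts were higher and 17 lower, and at 8-fold or more 30 were higher and 0 were lower on the loess scale. On the spike-in scale 94 were at least 4-fold higher and 321 lower, and 18 at least 8-fold higher and 8 lower. Other settings moved these counts too. At 4-fold or more they were 465 higher and 88 lower with Feature Extraction's processed signals. They were 281 and 66 with the sample channel alone, and 193 and 68 with each array centred on a median in place of loess. At 8-fold or more, the same settings gave 154 and 8, 79 and 2, and 38 and 1. The highest array of one group lay below the lowest of the other for 10848 transcripts, or 61.1% of those measured on every array, where chance gives 2.86% on average. Of the 1620 transcripts changed at least 2-fold, 1618 were separated in this way. Transcripts measured on the same arrays vary together, so each is not a separate piece of evidence against chance. Cell type markers were not tested. A different mix of cell types in the sorted groups therefore cannot be told apart from changes within dendritic cells.

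**Figure D2:**
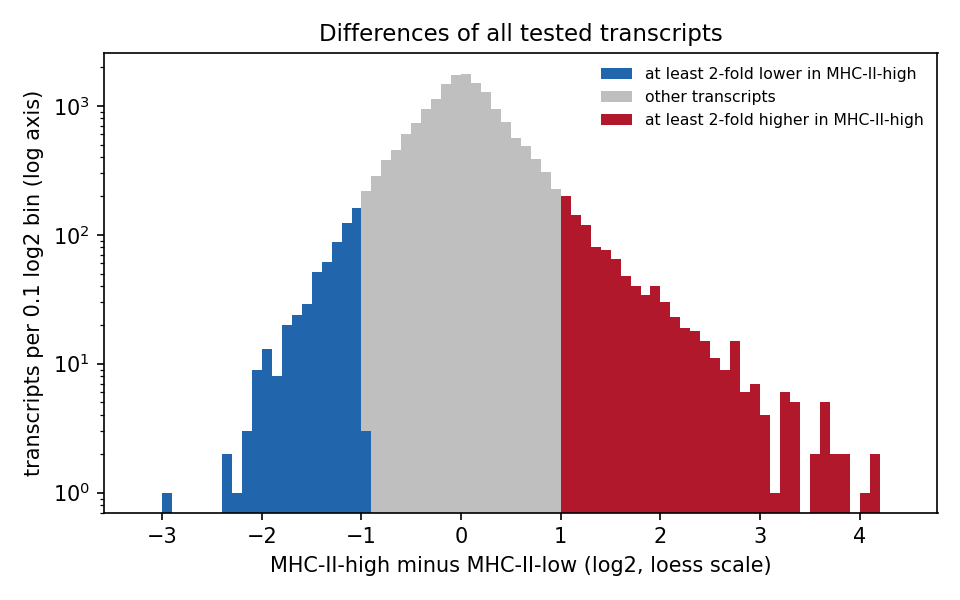
Number of transcripts (y axis, log scale) by their log2 difference, MHC-II-high minus MHC-II-low, in bins of 0.1 (x axis), for all 17755 transcripts tested. Red marks the 1024 transcripts that were at least 2-fold higher in MHC-II-high and blue the 596 that were at least 2-fold lower; the right tail reaches 4.198 and the left tail -2.94.

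The direction of small changes depended on how the arrays were scaled. Before loess, the median log2 ratio of kept probes was 0.53 ± 0.12 (SD, n = 4) in MHC-II-high and 0.74 ± 0.10 (SD, n = 4) in MHC-II-low. The difference of -0.21 log2 had an exact permutation p of 0.0286 (adjusted p = 0.0786 over the 11 measures) and was -0.13 within slide 1 and -0.20 within slide 2. With loess, 52.2% of changed transcripts were higher in MHC-II-high. With each array centred on a median in place of loess, 35.6% were higher. The median difference of all transcripts moved from 0.02 to -0.11 log2. The centring median was taken over all non-control spots, dim ones included, and not over the tested transcripts. The share of 35.6% depends on this choice as well as on the absence of loess. Around the tested transcripts' own median without loess, 1057 differences lay at least 1 log2 above and 1072 at least 1 log2 below. Scaling to the E1A spike-ins, control RNAs for which every array carries probes, moved the median difference to -0.57 log2 and left 9.44% of changed transcripts higher (7.54% with loess first). This scale was chosen after the data were seen. All transcripts of an array share the error of its spike-in value, so p-values on that scale are too small. The balance of larger changes moved too. With median centring 845 transcripts were at least 2-fold higher in MHC-II-high and 1425 at least 2-fold lower, and on the spike-in scale 400 were higher and 4075 lower. All 1024 transcripts at least 2-fold higher and all 596 at least 2-fold lower with loess were still called in the same direction on both scales. A shift in level of under 1 log2 cannot by itself reverse a 2-fold change. Counts and differences of transcripts are on the loess scale unless another is named.

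The reference RNA places these changes. The transcripts that were at least 2-fold higher in MHC-II-high had a median ratio to the reference of -0.19 log2 in MHC-II-low and of 1.36 in MHC-II-high, and 166 of the 1024 in MHC-II-low, against 601 in MHC-II-high, lay at least 2-fold over the reference. These transcripts were picked for being higher in MHC-II-high, and over all tested transcripts the shares were 13.1% in MHC-II-low and 14.2% in MHC-II-high. The transcripts at least 2-fold lower in MHC-II-high went the other way, from a median of 1.14 log2 in MHC-II-low to -0.10 in MHC-II-high, with 322 of the 596 at least 2-fold over the reference in MHC-II-low and 135 in MHC-II-high. A set of 240 transcripts lay at least 8-fold over the reference in both groups, and 32 of these changed at least 2-fold, 13 upwards and 19 downwards in MHC-II-high. A further 156 transcripts passed that limit in MHC-II-high alone and 97 in MHC-II-low alone, but 49 of the 156 and 44 of the 97 did not change by 2-fold.

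Some transcripts were well above background in one population only. The sample channel was well above background on all 4 MHC-II-high arrays and on no MHC-II-low array for 253 transcripts, and 246 of these were called higher in MHC-II-high. The reverse held for 53 transcripts, 51 of which were called lower in MHC-II-high. The calls use the same sample channel as the selection, so this agreement in direction is not separate support. These counts mark crossings of the background limit and do not show that a transcript was absent from the other population. No fold is given for single transcripts. A lower bound taken from the sample channel had a median of 1.46-fold for those called higher and 1.45-fold for those called lower. It exceeded the fold of the same probe's log ratios for 97 of the 297 transcripts called, so it is not a firm bound.

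The 8 arrays lay on 3 slides. Slide 1 held 1 MHC-II-high and 2 MHC-II-low arrays, slide 2 held 3 and 1, and slide 3 held a single MHC-II-low array. With slide as a block, 10562 transcripts changed, and 1608 changed at least 2-fold. Within slide 1 alone 9349 transcripts changed, 1789 of them at least 2-fold, and within slide 2 alone 8523 changed, 1643 of them at least 2-fold. Each of these within-slide counts rests on the assumption that the group with a single array varies like the other group. The slides share no array, but some replicate numbers occur on both. If these numbers mark shared cultures, the slides are not separate biological samples. Of the 1789 transcripts changed at least 2-fold within slide 1, 1787 had the same direction within slide 2, where independent signs would give 50.3%, and 1248 were again at least 2-fold different. Of the 1643 picked within slide 2, 1640 had the same direction within slide 1. The log2 difference of NM_011454 was 4.26 with slide as a block, 4.61 within slide 1 and 3.94 within slide 2. For NM_025359 these values were 4.12, 4.04 and 4.197. They were -2.91, -2.70 and -3.10 for NM_026439, and -2.48, -2.59 and -2.38 for NM_013652.

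The E1A spike-ins stood higher on all 4 MHC-II-high arrays than on any MHC-II-low array. Relative to the median transcript, the 10 spike-in probes had a mean log2 ratio of 0.42 ± 0.19 (SD, n = 4) in MHC-II-high and -0.19 ± 0.07 (SD, n = 4) in MHC-II-low. The difference of 0.61 log2 passed an exact permutation test (two-sided, p = 0.0286, the smallest that 4 against 4 arrays allow), and did not pass after adjustment over the 11 measures (adjusted p = 0.0786). The test takes the arrays as unpaired. If the replicate numbers pair the samples, the paired exact p would be 0.125, the smallest that 4 pairs allow. Each of the 10 probes separated the groups, with differences from 0.39 to 0.75 log2. The difference was 0.76 log2 within slide 1 and 0.47 within slide 2, each with a single array in one group.

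**Figure D3:**
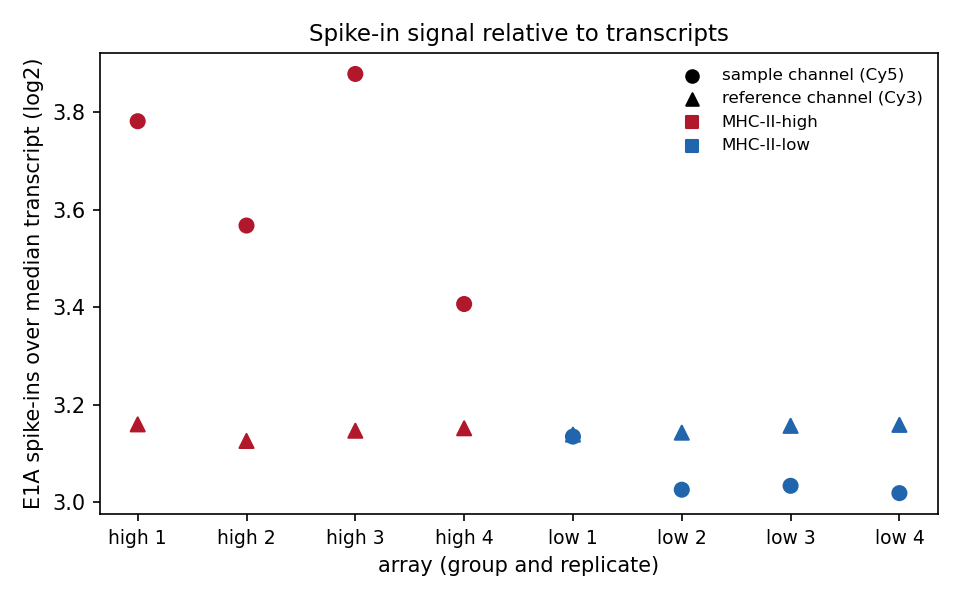
Mean log2 signal of the 10 E1A spike-in probes over the median transcript (y axis) on each array (x axis, group and replicate), for the sample channel (circles) and the reference channel (triangles). In the sample channel the MHC-II-high arrays lie between 3.41 and 3.88 and the MHC-II-low arrays between 3.02 and 3.135, while the reference channel stays between 3.13 and 3.16 on every array.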

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

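The E1A spike-ins stood out in control probes that the comparison of transcripts does not use, and the tests of them below were chosen after the shift was seen. Relative to transcripts they were higher in MHC-II-high by 0.608 log2, and all 4 MHC-II-high arrays lay above all 4 MHC-II-low arrays. The reference channel argues against an origin on the reference side, since its spike-in signal over transcripts differed by -0.0029 log2 between groups. Within slide 1 the shift was 0.76 log2 and within slide 2 it was 0.47, but each of these has a group with a single array, and the SD between MHC-II-high arrays was 0.19, so a part from the slide stays open. Also open is less labelled transcript RNA per spike-in in the MHC-II-high samples, which may come from the amount or quality of the RNA at labelling or from a lower mRNA content of these cells. The median transcript differed by -0.57 log2 on the spike-in scale, which restates the shift and favours none of these. The labels do not state how much spike-in was added, and the group and the handling of its RNA cannot be told apart.

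Within groups of 4 arrays, 30 sets of values were searched for an array far from its group: the measures kept per array, which cover signals, backgrounds, probes above background, outlying spots and spike-ins, and the 4 named transcripts. Chance gives about 1 in 20, and 4 were found. The median reference signal of MHC-II-high replicate 2 was 99, where the other arrays of its group had 88.5 to 90. The log2 ratio of NM_025359 in MHC-II-high replicate 3 was 1.52, where the other arrays of its group had 1.79 to 1.84. In MHC-II-low replicate 1, the only MHC-II-low array on slide 2, 164 spots were marked as outliers, against 118 to 125 on the other arrays of its group. Its spike-in signal over transcripts in the sample channel was 3.135 log2, against 3.02 to 3.03.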

How the results depend on the processing

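The spike-in scales and the within-slide comparisons were chosen after the data were seen. The 4 named transcripts kept their direction and an adjusted p under 0.05 in each of 28 settings (highest 7.81e-05). NM_011454 ranged from 3.52 to 4.64 log2, NM_025359 from 3.45 to 4.47, NM_026439 from -3.95 to -2.70 and NM_013652 from -3.34 to -2.29. The number of changed transcripts stayed within 1.5 times 11924 except in the test against a log2 difference of 1, which by its construction called fewer (811, of which 73.4% were higher in MHC-II-high). Leaving out each array in turn gave 11206 to 11833. The number changed at least 2-fold was 2740 with Feature Extraction's processed signals, 4475 on the spike-in scale and 4311 with loess before that scale, and stayed within 1.5 times 1620 otherwise, leaving aside the test against a log2 difference of 1.

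The share of changed transcripts that were higher in MHC-II-high reversed to 35.6% with median centring, 48.1% with the sample channel alone, 9.44% on the spike-in scale and 7.54% with loess before it (median difference -0.66 log2). It moved by more than 0.36 points, the SD over left-out arrays, to 53.8% with processed signals, 52.8% with a normexp offset of 16, 51.7% with scale normalization, 51.0% with probes above background on all 8 arrays, 51.4% with the mean of a transcript's probes and 51.6% with array weights; the cause was not tested. Left-out arrays gave 51.7% to 52.7%. Among 2-fold changes the share reversed to 37.2% with median centring, 8.94% on the spike-in scale and 7.14% with loess before it. It moved by more than their SD of 0.82 points to 62.4% without background correction, 62.2% with processed signals, 64.1% with scale normalization, 56.2% with the sample channel alone, 61.3% with the filter on all 8 arrays and 62.0% within slide 1. Left-out arrays gave 61.5% to 64.4%. Aquantile normalization leaves log ratios as they are, so it could move nothing.

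With the replicate number as a block, 11933 transcripts changed, 1620 of them at least 2-fold. Deviations from the group means of same-numbered arrays correlated at 0.21, 0.16, 0.15 and -0.13 across transcripts. Arrays with different numbers gave -0.26 to 0.22, and 4 of 8 arrays correlated best with their own number. Same-numbered arrays never shared a slide, so this check cannot exclude that the numbers pair the samples. The main fit took the samples as unpaired. Titles share a letter within each number, and no label says what it marks. If the numbers do pair the samples, the spike-in shift was above 0 in 4 of 4 pairs and its paired exact p would be 0.125, the smallest that 4 pairs allow. The gene lists and the genes fixed by symbol were not run under any setting, for want of gene names. Signal over background limits the 2259 transcripts that were not above it on every array.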

Other observations

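In this part, the tests of brightness, of the spike-in scale and of 2-fold changes without loess were chosen after the results were seen.

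The share of rises among 2-fold changes was counted by kind of accession, on the loess scale first. Among transcripts with a curated RefSeq accession (those beginning NM), 691 of the 1183 changed at least 2-fold were higher in MHC-II-high, or 58.4%. Among cDNA accessions beginning AK the share was 78.7% (174 of 221), among predicted RefSeq accessions it was 82.6% (38 of 46), and among other sequence accessions it was 73.6% (92 of 125). Array-specific or consensus IDs had 64.5% (20 of 31) and Ensembl transcripts 64.3% (9 of 14). With median centring in place of loess these 6 shares were, in the same order, 32.4%, 59.5%, 48.7%, 47.2%, 41.0% and 36.4%. On the spike-in scale they were 8.06%, 14.4%, 11.5%, 11.7%, 4.96% and 12.8%, so their order depended on the scale. The difference between kinds was not tested.

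The number of changed transcripts was set against the other ways to divide the 8 arrays into 4 and 4. Only 1 of the 35 splits, the real one, gave 11924 transcripts, and the highest of the others gave 0. The same 1 of 35 splits gave 1620 transcripts changed at least 2-fold, where the highest other gave 0. For both counts that is 2.86% of splits, the lowest share these arrays allow. It lies under the limit of 0.05, but with so few splits a chance division is not excluded. The splits also take the arrays as unpaired. If the replicate numbers pair the samples, the smallest exact p that 4 pairs allow is 0.125, above that limit. The other splits mix the groups, so their counts of 0 do not measure how strong the difference is. With slide as a block, 100% of the 1620 transcripts were called in the same direction, which argues against the slide as their origin.

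Whether 2-fold rises outnumber 2-fold falls depended on processing. Dim signals do not account for the whole excess, since rises were 59.2% of 2-fold changes among transcripts of above-median brightness (584 against 403). The share was higher, 69.5%, among the dimmer ones (440 against 193), so a part from dim signals stays open. On the spike-in scale they were 8.94%, but that scale moves every transcript of an array by one amount, so the value restates the spike-in shift and leaves open whether the level of the scale gives the excess. The loess curve is a candidate explanation, since without it rises were 49.6% of differences at least 1 log2 from their own median. With loess, 986 lay at least 1 log2 above their own median and 634 below. At 2 log2 or more from that median, rises were 81.2% without loess (216 against 50). With loess the counts were 175 against 20. The curve therefore does not account for the whole excess of the largest rises around the median transcript, and a part from it stays open. On the spike-in scale itself 94 transcripts were at least 4-fold higher and 321 at least 4-fold lower.

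Different probes of one accession did not always move together. Of 3946 accessions with more than 1 kept probe, 2260 had at least 2 probes called, and 112 of these (4.96%) had probes called in both directions. There were 0 accessions with probes changed at least 2-fold in both directions, and the probes of 94 accessions differed by more than 1 log2.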
